A study of Homo sapiens with 48 samples.

How the data were processed

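RNA of differentiating pluripotent stem cells was sequenced in bulk, with polyA selection and TruSeq paired-end libraries per the labels' protocols. Per the submitters' processing notes, reads were aligned to GRCh38 with STAR 2.7.3a and differential expression was run with DESeq2; its version is not given in the sources used here. The deposited files hold 1 table of gene counts per library in the layout of STAR, and the unit of every value used is a read count as the authors deposited it. Each table has an unstranded and 2 stranded columns; the reverse-strand column held 94.32 to 95.43% of stranded gene counts and was used, so the strand was settled from the data. The labels list 48 libraries. The library labelled day 16 replicate 4 (J2) held 0 counts in every gene, which left 2 libraries, both labelled H9, on day 16, where the design had allowed for 3. The library of a TH reporter line on day 31 entered no comparison. The file of day 3 replicate 4 is named for day 4, and the label was followed.

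The tables of days 0 to 21 list 58788 genes and those of days 23 to 40 list 60719, so 2 annotations were used upstream; 58616 genes common to both were kept, which hold 92.94 to 95.66% of the gene counts of late libraries. Mitochondrial genes were absent from the early tables and held 4.31 to 7.03% of late counts, and fell out in this way. Symbols, types and coordinates came from GENCODE 29, which matched 58348 genes. Gene counts ranged from 21949466 to 42878200 per library; 24129 to 28814 genes were detected in early libraries and 25572 to 29521 in late ones. Reads outside genes were 6.87 to 15.61% early and 5.02 to 9.59% late, and were kept out of library sizes. Over 63 replicate pairs, the chi-square per degree of freedom was 19.02 to 568.43 and r was 0.8561 to 0.9945, so spread between libraries was far above counting error. The 95% intervals and the floor of 3 counts given with near-absent genes cover counting error only.

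Counts were fitted with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr by day, 23055 genes tested) in R 4.3.3, with 1 mean for each of 13 days and 2 line terms, 1 per set. Interactions used 1 mean per day and label. Adjusted p-values are Benjamini-Hochberg over all tested genes of 1 comparison, with a threshold of 0.05. P-values measure spread between libraries, taking days of 1 replicate number as independent. Comparisons were 6 main day pairs, 9 adjacent steps, labels within each set and 2 interactions. CPM values use TMM-scaled library sizes. A gene with 0 counts in a group is given as at least a fold against a floor of 3 counts over that group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count of 1, preset correlation of 0.01), adjusted over the 30 lists. A list that passed in this test with all libraries also passed with an estimated correlation where no p-value with that correlation is given; list values with the replicate block or without late differentiation 1 were not tested with that correlation.

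The 30 lists, 340 genes, were fixed before the data were examined, as were the comparisons, the main settings and the rule for named genes. They cover pluripotency; primitive streak, mesoderm and axial progenitor; neural plate border; neural crest; HOX paralogs 1 to 5, 6 to 9 and 10 to 13; sympathoadrenal transcription factors; catecholamine synthesis and storage; neuronal; cholinergic; chromaffin; Schwann cell precursor and glia; sensory neuron; mesenchyme and fibroblast; melanocyte; skeletal muscle; central nervous system progenitor; epithelium and endoderm; endothelium and blood; proliferation; BMP, WNT, hedgehog, NODAL and TGF-beta, and FGF targets; cholesterol synthesis; neuroblastoma-associated genes; stress response; and hypoxia and glycolysis. The rule names 27 key genes, up to 4 passing members of each list in its main direction and 1 in the other, and the 5 strongest genes per direction with a mean of at least 10 CPM and no overlap between groups. The rule allows 646 pairs of gene and comparison; the text names only part of these, picked after their values were seen and with some genes first left out because their calls moved, so the genes named are more stable than the rest. Other genes chosen after their values were seen are marked as such.

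Alternatives planned before the data were examined were DESeq2 size factors as scaling, no low-count filter, DESeq2 1.42.0 (Wald test), a replicate block, no line covariate, only the libraries of the 2 days, an absolute log2 change of at least 1, counts summed over days, each library or replicate number left out, camera with an estimated correlation and fry. Unstranded counts, libraries labelled H9 only, late differentiation 1 left out and the lists with the replicate block were added after the data were seen. The sources do not say if a replicate number names 1 culture followed over days. After removal of day means, residuals of late libraries with the same number correlated (mean r 0.65, minimum 0.24 over 60 pairs). Other numbers of the same label had a mean of 0.16. The early means were 0.29 (minimum 0.02 over 24 pairs) and 0.29. Simulated counts with 200 changed genes were passed through the same code. With edgeR, recovery at 2-, 4-, 8- and 16-fold among 23055 genes was 6, 58, 80 and 92% for day 35 against day 23, with 4.1% false calls; 4, 38, 64 and 92% for day 21 against day 16, with 4.8%; 40, 90, 94 and 94% for H9 against J2 in days 23 to 40, with 3%; and 0, 10, 36 and 54% for the interaction of days 23 and 35, with 3.8%. DESeq2 gave 12, 62, 80 and 88% for day 35 against day 23, with 11%. The rates need not hold for real libraries: late ones correlated by number (a false split gave 3452 genes) and day 16 had 1 label. Sex-linked transcripts were not analysed.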

Results

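Bulk RNA-seq covered a 40-day differentiation of human pluripotent stem cells along the sympathoadrenal lineage, in which cells labelled as the embryonic line H9 or the induced line J2 were taken on 13 days. In the labels' protocols, cells received FGF2, the TGF-beta receptor inhibitor SB431542, the GSK3 inhibitor CHIR and BMP4 for 2 days, then SB431542 and CHIR until neural crest cells were enriched by sorting on day 16. Sorted cells grew as spheres with FGF2 and CHIR, were plated, received BMP4 and SHH for 4 days and then ascorbic acid. The series held 48 labelled libraries, of which 47 had reads, and 46 of these, 25 labelled H9 and 21 labelled J2, entered the comparisons. Days 0, 3, 7, 21, 23, 25, 27, 29, 31 and 35 had n = 4 libraries each, 2 per label; days 11, 16 and 40 had n = 2. Those of days 11 and 16 were all labelled H9, and 1 further library from a TH reporter line on day 31 was described alone. Libraries of days 0 to 21 and of days 23 to 40 formed 2 sets with separate replicate numbering. Gene counts per library ranged from 21949466 to 42878200. Levels are mean ± SD in CPM (read counts scaled to the effective library size) over n = 4 libraries unless another n is given, log2 fold changes are the later day over the earlier, and p-values are from edgeR, adjusted by Benjamini-Hochberg. Genes named were picked from those a fixed rule allows after their values were seen, with calls that held against left-out libraries preferred: 8 of 73 passing calls named from the rule lost the threshold with 1 library left out, against 182 of 449 passing calls not named. Of 9 further passing calls, chosen outside the rule, 6 lost it with 1 library or replicate number left out.

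The level of POU5F1 dropped within the first week, that of SOX10 was highest on day 21 and that of TH on day 40. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731), which holds the pluripotent state, stood at 1353 ± 492 CPM on day 0, 22.8 ± 4.05 on day 7 and 0.0572 ± 0.0524 on day 35. SOX10 (ENSG00000100146, chromosome 22, 37970686 to 37987422), required for migrating neural crest and glia, read 35.6 ± 56.7 CPM on day 7, 374 ± 88.6 on day 16, 732 ± 272 on day 21 and 27.7 ± 13.4 on day 35. FOXD3 (ENSG00000187140, chromosome 1, 63323041 to 63325126), a neural crest specifier, read 0.105 ± 0.0828 CPM on day 3 and 58.3 ± 23.2 (n = 2, both labelled H9) on day 16. HOXC9 (ENSG00000180806, chromosome 12, 53994895 to 54003337), a trunk-level paralog, read 0.581 ± 1.09 CPM on day 3 and 23.02 ± 11.6 on day 23.

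HAND2 (ENSG00000164107, chromosome 4, 173524969 to 173530229), which maintains noradrenergic identity, read 4.65 ± 3.85 CPM on day 23, 119 ± 107 on day 27 and 441 ± 372 on day 31. TH (ENSG00000180176, chromosome 11, 2163929 to 2171877), the rate-limiting enzyme of catecholamine synthesis, read 3.44 ± 4.33 CPM on day 31, 1.37 ± 2.11 on day 35 and 30.3 ± 12.9 (n = 2) on day 40. DBH (ENSG00000123454, chromosome 9, 133635348 to 133659344), which makes noradrenaline, read 11.9 ± 15.01 CPM on day 35 and 316 ± 48.5 (n = 2) on day 40.

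**Figure D1:**
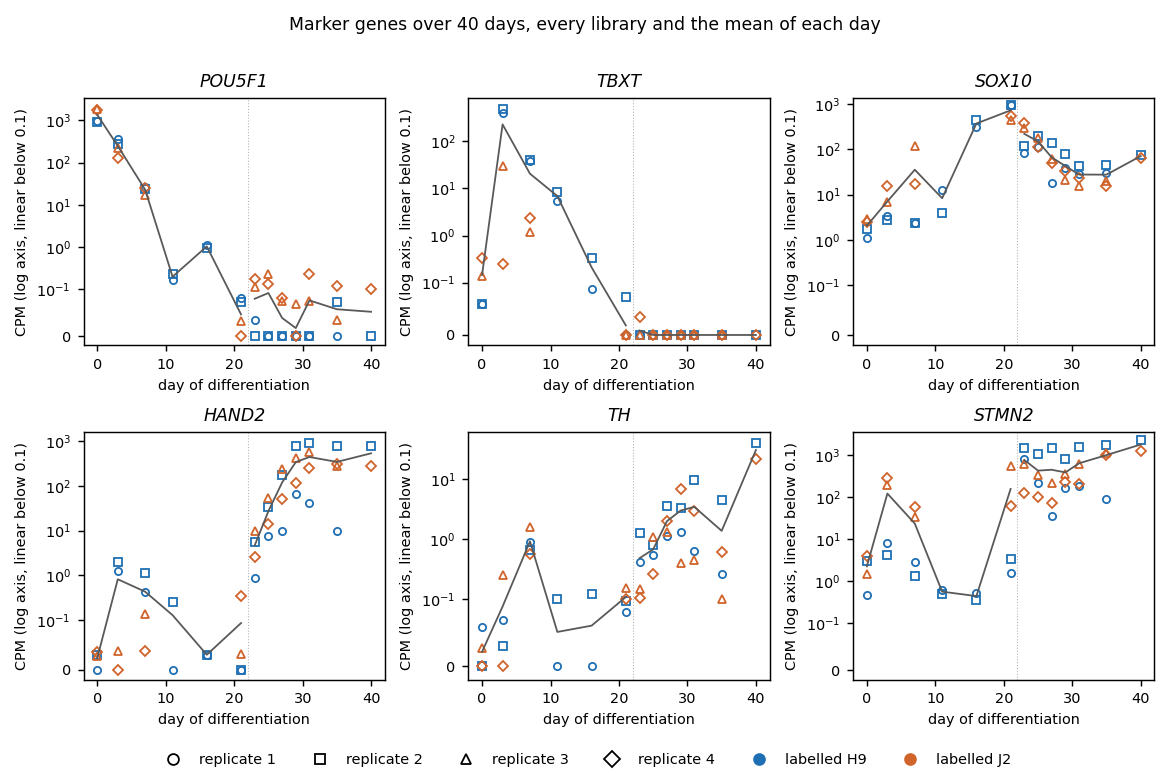
CPM (log axis) against day for 6 marker genes; points are libraries, with shape for replicate number and colour for label, and lines are means of each day within each set. POU5F1 went from 1353 CPM on day 0 to 0.0572 on day 35, while HAND2 went from 4.65 on day 23 to 441 on day 31.

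Between day 0 and day 3 the cells lost pluripotency transcripts and turned on primitive streak, axial progenitor, neural plate border and HOX genes. POU5F1 fell from 1353 ± 492 to 247 ± 95.8 CPM (log2 fold change −2.50, SE 0.33, adjusted p = 6.90e-07). The NODAL co-receptor TDGF1 fell from 502 ± 62.3 to 8.95 ± 9.23 (log2 −6.50, adjusted p = 4.76e-05). FOXD3, expressed in stem cells as well as neural crest, fell from 8.67 ± 3.19 to 0.105 ± 0.0828 CPM (log2 fold change −6.47, SE 1.24, adjusted p = 0.000129). TBXT, a mesoderm and axial progenitor factor, rose from 0.145 ± 0.127 to 229 ± 249 CPM (log2 fold change 9.01, SE 1.48, adjusted p = 0.000152). CDX2, which turns on trunk HOX genes, rose from 0.0453 ± 0.0287 to 215 ± 127 (log2 12.20, adjusted p = 6.43e-09). On day 3 TBXT read 405 and 481 CPM in the libraries labelled H9 and 30.04 and 0.253 in those labelled J2, the last (replicate 4) not above its day 0 value of 0.327.

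PAX3, a neural plate border factor, rose to 141 ± 121 CPM by a ratio of 5590 with a 95% counting interval of 1910 to 27100 (3680 without day 3 replicate 3 to 13300 without day 0 replicate 4). SNAI2, a driver of delamination, rose from 0.867 ± 0.291 to 64.5 ± 96.9 CPM (log2 5.79, adjusted p = 3.86e-05). HOXB9 reached 383 ± 244 CPM, a ratio of 25700 with a 95% counting interval of 7120 to 213000 (12700 without day 0 replicate 1 to 29200 without day 3 replicate 1), and HOXC6 23.2 ± 30.4 CPM from 0 counts, at least 1050-fold (413 without day 3 replicate 3 to 1340 without day 3 replicate 1). The NODAL antagonist LEFTY1 fell to 0 counts, at least 129-fold (85.4 without day 0 replicate 3 to 169 without day 0 replicate 2), in the days with SB431542.

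MSMO1, a cholesterol synthesis enzyme, rose from 238 ± 97.6 to 1273 ± 1640 (log2 2.34, adjusted p = 0.000487; log2 0.93, adjusted p = 0.0246 without day 3 replicate 4).

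Fixed lists were tested with camera. Pluripotency genes fell: 1 of 14 up and 12 down, adjusted p = 5.85e-09. NODAL and TGF-beta targets fell: 1 of 8 up and 5 down, adjusted p = 0.000347. Primitive streak, mesoderm and axial progenitor genes rose: 12 of 15 up and 0 down, adjusted p = 3.98e-09. Neural plate border genes rose: 8 of 11 up and 0 down (9 and 0 over the list alone), adjusted p = 1.06e-08. WNT targets rose: 8 of 10 up and 0 down, adjusted p = 4.36e-08. HOX paralogs 1 to 5 rose: 15 of 15 up and 0 down, adjusted p = 1.79e-34. Their median log2 change was 11.42, 9.08 with members without reads at their bound. HOX paralogs 6 to 9 rose: 11 of 12 up and 0 down, adjusted p = 1.61e-17. Their median log2 change was 11.12, 8.92 with members without reads at their bound. HOX paralogs 10 to 13 rose: 6 of 8 up and 0 down, adjusted p = 0.0292, but adjusted p = 0.26 with an estimated correlation. Their median log2 change was 4.66, 3.37 with members without reads at their bound. BMP targets rose: 4 of 9 up and 0 down (5 and 0 over the list alone), adjusted p = 0.0247, but adjusted p = 0.578 with an estimated correlation. Hypoxia and glycolysis genes rose: 8 of 13 up and 0 down (10 and 0 over the list alone), adjusted p = 0.000497, but adjusted p = 0.468 with an estimated correlation. Proliferation genes fell: 0 of 16 up and 3 down, adjusted p = 0.0205, but adjusted p = 0.766 with an estimated correlation. Counts adjusted over the list alone were equal to these for the other lists named. Median, mean and test of the Schwann cell, central nervous system and FGF target lists differed in sign, and none of these passed.

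With edgeR, 7444 of 23055 tested genes (4059 higher and 3385 lower) changed between days 0 and 3. Of 104 passing genes that the rule allows here, 29 lost their call with 1 library left out. SOX10 (7.09 ± 5.85 against 2.06 ± 0.808 CPM, log2 1.57, adjusted p = 0.106), GATA3 (26.6 ± 44.5 against 0.489 ± 0.555, log2 3.48, adjusted p = 0.051; adjusted p = 0.00602 to 0.25 with 1 library left out) and MKI67 (219.6 ± 147 against 424 ± 114, log2 −1.14, adjusted p = 0.0503; adjusted p = 0.0413 to 0.203 with 1 library left out) did not pass. Settings that ended a call (adjusted p) were the libraries of the 2 days only for MSMO1 (0.0914). Settings that gave a call (adjusted p) were the libraries of the 2 days only for SOX10 (0.0192), no line covariate for GATA3 (0.00156), DESeq2 for GATA3 (0.0103) and MKI67 (0.0306), no low-count filter for GATA3 (0.0158) and MKI67 (0.0159), DESeq2 size factors for MKI67 (0.0459) and the replicate block for MKI67 (0.0371). The 4 libraries of a day held 2 libraries per label, so variation between cell lines was estimated from 2 cultures each.

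From day 3 to day 7 pluripotency genes fell further and HOX genes of trunk paralogs rose. POU5F1 fell from 247 ± 95.8 to 22.8 ± 4.05 CPM (log2 fold change −3.43, SE 0.34, adjusted p = 4.99e-08). TDGF1 fell from 8.95 ± 9.23 to 0.243 ± 0.103 (log2 −4.68, adjusted p = 0.00739; adjusted p = 0.16 with DESeq2). HOXA9, which sets trunk-level identity, rose from 2.15 ± 3.28 to 34.7 ± 14.7 CPM (log2 4.19, adjusted p = 2.08e-05). HOXC9 rose from 0.581 ± 1.09 to 8.53 ± 7.22 CPM (log2 3.95, adjusted p = 0.00251; log2 7.24, adjusted p = 1.10e-05 without day 3 replicate 3).

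Pluripotency genes fell: 0 of 14 up and 4 down (0 and 7 over the list alone), adjusted p = 7.54e-08. HOX paralogs 6 to 9 rose: 7 of 12 up and 0 down (9 and 0 over the list alone), adjusted p = 8.38e-18. HOX paralogs 1 to 5 rose: 5 of 15 up and 0 down (5 and 1 over the list alone), adjusted p = 4.42e-05, but adjusted p = 0.677 with an estimated correlation. Cholesterol synthesis genes fell: 0 of 16 up and 7 down (0 and 11 over the list alone), adjusted p = 7.07e-06, but adjusted p = 0.677 with an estimated correlation. MSMO1 of this list fell from 1273 ± 1640 to 318 ± 87.8 CPM (log2 −1.92, adjusted p = 0.0165), and day 3 replicate 4 stood apart at 3732; the call was lost without day 3 replicate 4 (log2 −0.51, adjusted p = 0.38), day 7 replicate 3 (log2 −1.66, adjusted p = 0.0851) or day 7 replicate 4 (log2 −1.74, adjusted p = 0.0648). Mesenchyme and fibroblast genes stood at adjusted p = 0.143 (1 of 13 rose and 0 fell, 3 and 0 over the list alone), and at adjusted p = 0.0278 with the replicate block. For the other lists named, adjustment over the list alone gave equal counts. Median, mean and test differed in sign for the neural plate border, HOX paralogs 10 to 13, catecholamine, neuronal and stress response lists, none of which passed. On day 7 the neural crest list was higher in libraries labelled J2 (median log2 2.29, adjusted p = 2.28e-05, but adjusted p = 0.232 with an estimated correlation), a test chosen after the values were seen. SOX10 read 2.37 and 2.42 CPM in libraries labelled H9 and 119.9 and 17.6 in those labelled J2.

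With edgeR, 1392 of 23055 tested genes (750 higher and 642 lower) changed between days 3 and 7 (658 and 760 with DESeq2 size factors, 596 and 630 with no low-count filter, 887 and 1083 with DESeq2 and 183 and 202 in libraries of the 2 days only). Of 51 passing genes that the rule allows here, 28 lost their call with 1 library left out. Left-out libraries moved this to 329 higher and 338 lower without day 3 replicate 1, 454 and 409 without day 3 replicate 2, 519 and 324 without day 7 replicate 1, 453 and 263 without day 7 replicate 2, 516 and 366 without day 7 replicate 3. FOXD3 (6.73 ± 11.1 against 0.105 ± 0.0828 CPM, log2 5.51, adjusted p = 0.00755) lost its call without day 7 replicate 3 (log2 3.23, adjusted p = 0.0877), and TBXT (20.6 ± 21.7 against 229 ± 249, log2 −3.34, adjusted p = 0.0599; log2 −3.78, adjusted p = 0.00645 without day 3 replicate 4) and SOX10 (35.6 ± 56.7 against 7.09 ± 5.85, log2 1.90, adjusted p = 0.133) did not pass. Settings that ended a call (adjusted p) were the libraries of the 2 days only for HOXA9 (0.0548), HOXC9 (0.0632), MSMO1 (0.344) and TDGF1 (0.0685). Settings that gave a call (adjusted p) were no low-count filter for SOX10 (0.0486) and TBXT (0.00101).

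From day 7 to the sort on day 16, neural crest and glial genes rose and axial progenitor genes fell. If day 16 libraries hold sorted cells, sorting and time cannot be separated in tests against that day. Day 16 had only libraries labelled H9, so levels are given for those libraries on both days (n = 2 each), while log2 values and tests used all libraries and differ from the ratio of these levels. SOX10 rose from 2.396 ± 0.0361 to 374 ± 88.6 CPM (log2 fold change 4.95, SE 1.00, adjusted p = 0.000991). TFAP2B, a neural crest and sympathoadrenal factor, rose from 0.114 ± 0.0401 to 844 ± 82.7 (log2 9.77, adjusted p = 0.000597). POU5F1 fell from 24.8 ± 2.53 to 1.03 ± 0.13 CPM (log2 fold change −4.43, SE 0.51, adjusted p = 5.25e-07). HOXB4 fell from 182 ± 29.8 to 19.7 ± 5.47 CPM (log2 −2.75, adjusted p = 0.000253). CDX2 fell from 141 ± 5.96 to 8.41 ± 7.04 CPM (log2 −4.84, adjusted p = 0.00386; log2 −4.24, adjusted p = 0.112 without day 16 replicate 1).

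Neural crest genes rose: 8 of 14 up and 0 down (9 and 0 over the list alone), adjusted p = 2.34e-08. Schwann cell precursor and glia genes rose: 9 of 11 up and 0 down, adjusted p = 1.21e-07. Primitive streak, mesoderm and axial progenitor genes fell: 0 of 15 up and 11 down (0 and 15 over the list alone), adjusted p = 6.70e-12. Epithelium and endoderm genes fell: 0 of 11 up and 7 down (0 and 9 over the list alone), adjusted p = 1.67e-08. Melanocyte genes rose: 4 of 8 up and 0 down (5 and 0 over the list alone), adjusted p = 0.000143, but adjusted p = 0.164 with an estimated correlation. Neuroblastoma-associated genes rose: 3 of 10 up and 0 down, adjusted p = 0.0441, but adjusted p = 0.558 with an estimated correlation. HOX paralogs 1 to 5 fell: 0 of 15 up and 6 down (0 and 11 over the list alone), adjusted p = 4.60e-05, but adjusted p = 0.374 with an estimated correlation. Hedgehog targets fell: 0 of 7 up and 4 down (0 and 5 over the list alone), adjusted p = 0.0361, but adjusted p = 0.396 with an estimated correlation. Stress response genes fell: 0 of 12 up and 4 down, adjusted p = 0.0361, but adjusted p = 0.579 with an estimated correlation. The other lists named had equal counts when adjusted over the list alone. For the neural plate border, HOX paralogs 10 to 13, sensory neuron and endothelium lists, which did not pass, median, mean and test differed in sign.

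With edgeR, 2997 of 23055 tested genes (1585 higher and 1412 lower) changed between days 7 and 16 (1183 and 1218 with a change of at least 2-fold, 1154 and 1442 with no low-count filter, 1379 and 1514 with unstranded counts and 1233 and 1511 without day 7 replicate 4). Of 66 passing genes that the rule allows here, 43 lost their call with 1 library left out. The count was 458 higher and 226 lower without day 16 replicate 1, 800 and 626 without day 16 replicate 2, 834 and 1121 without day 7 replicate 1, 1037 and 1015 without day 7 replicate 2. FOXD3 (from 0.0285 ± 0.0403 to 58.3 ± 23.2 CPM, log2 4.29, adjusted p = 0.0319) stood at log2 10.88, adjusted p = 2.29e-05 in libraries labelled H9 only and lost its call without day 16 replicate 1 (log2 4.58, adjusted p = 0.0965), day 16 replicate 2 (log2 3.74, adjusted p = 0.145), day 7 replicate 1 (log2 3.09, adjusted p = 0.114), day 7 replicate 2 (log2 3.17, adjusted p = 0.122) or day 7 replicate 4 (log2 4.02, adjusted p = 0.0652). Settings that ended a call (adjusted p) were the libraries of the 2 days only for FOXD3 (0.276), HOXB4 (0.0855), SOX10 (0.156) and TFAP2B (0.28) and no line covariate for TFAP2B (0.137).

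From day 16 to day 21, after sorting and sphere culture, epithelial and central nervous system progenitor genes fell as lists. Levels are those of libraries labelled H9 (n = 2 each), while log2 values and tests used all libraries. These again took the label difference as equal on all early days. DLX5 of the plate border fell from 46.8 ± 26.2 to 3.01 ± 0.948 CPM (log2 fold change −4.37, SE 0.75, adjusted p = 0.000265). The Notch target HES5 fell from 3.09 ± 0.943 to 0.10 ± 0.0653 (log2 −4.81, adjusted p = 0.00449). The epithelial junction gene CLDN4 fell from 7.31 ± 5.903 to 0.425 ± 0.0837 CPM (log2 −4.57, adjusted p = 4.18e-05). The adhesion gene EPCAM fell from 13.9 ± 8.28 to 0.189 ± 0.0772 (log2 −4.40, adjusted p = 1.41e-05). CA9, a hypoxia-induced carbonic anhydrase, fell from 4.35 ± 1.66 to 0.246 ± 0.272 CPM (log2 −4.20, adjusted p = 0.00243; log2 −4.11, adjusted p = 0.0577 in libraries labelled H9 only). UNC80, a part of the sodium leak channel of neurons, rose from 0.105 ± 0.0231 to 5.97 ± 3.49 CPM (log2 7.41, adjusted p = 0.000552). GLI1 rose from 0.464 ± 0.0716 to 1.87 ± 0.177 CPM (log2 3.59, adjusted p = 0.0188), and the call was lost without day 16 replicate 1 (log2 3.51, adjusted p = 0.165) or replicate 2 (log2 3.83, adjusted p = 0.123) and in libraries labelled H9 only (log2 2.02, adjusted p = 0.182).

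Epithelium and endoderm genes fell: 0 of 11 up and 6 down (0 and 7 over the list alone), adjusted p = 0.00011. Central nervous system progenitor genes fell: 0 of 7 up and 4 down (0 and 6 over the list alone), adjusted p = 0.000659. Hypoxia and glycolysis genes fell: 0 of 13 up and 7 down (0 and 10 over the list alone), adjusted p = 1.14e-05, but adjusted p = 0.375 with an estimated correlation. Pluripotency genes fell: 0 of 14 up and 3 down, adjusted p = 0.012, but adjusted p = 0.186 with an estimated correlation. Neural plate border genes fell: 0 of 11 up and 2 down, adjusted p = 0.0131, but adjusted p = 0.375 with an estimated correlation. HOX paralogs 1 to 5 fell: 0 of 15 up and 1 down, adjusted p = 0.0278, but adjusted p = 0.931 with an estimated correlation. Neuronal genes rose: 2 of 16 up and 0 down (8 and 0 over the list alone), adjusted p = 0.0313, but adjusted p = 0.931 with an estimated correlation. Adjusted over the list alone, the other lists named had equal counts. Median, mean and test differed in sign for the neural crest, catecholamine, mesenchyme, skeletal muscle, endothelium, WNT, NODAL and stress response lists, which did not pass.

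With edgeR, 2766 of 23055 tested genes (1259 higher and 1507 lower) changed between days 16 and 21 (2068 and 1342 in libraries labelled H9 only). Of 52 passing genes that the rule allows here, 37 lost their call with 1 library left out. Single libraries moved this to 253 higher and 692 lower without day 16 replicate 1, 272 and 429 without day 16 replicate 2, 778 and 1003 without day 21 replicate 1. SOX10 (732 ± 272 against 374 ± 88.6 CPM, log2 0.59, adjusted p = 0.699) and STMN2 (158 ± 274 against 0.448 ± 0.119, log2 4.06, adjusted p = 0.105) did not pass, with 4 libraries on day 21 against 2. Settings that ended a call (adjusted p) were the libraries of the 2 days only for CA9 (0.118), CLDN4 (0.0542), DLX5 (0.262), EPCAM (0.0905), GLI1 (0.0921) and UNC80 (0.064) and no line covariate for CA9 (0.0576) and DLX5 (0.266). Settings that gave a call (adjusted p) were no line covariate for STMN2 (0.0301), DESeq2 for STMN2 (0.00925) and no low-count filter for STMN2 (0.0378).

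Between days 23 and 35 PHOX2A, HAND2 and RET rose, while SOX10 and NEUROD1 fell. PHOX2A, a homeobox gene of autonomic precursors, rose from 0.822 ± 0.757 to 62.5 ± 81.4 CPM (log2 fold change 6.04, SE 1.34, adjusted p = 0.00175). HAND2 rose from 4.65 ± 3.85 to 343 ± 320.1 (log2 fold change 6.16, SE 1.21, adjusted p = 0.000523). RET, the GDNF receptor of autonomic neurons, rose from 9.39 ± 7.82 to 840.4 ± 631 (log2 6.54, adjusted p = 0.000105). The acetylcholine-making enzyme CHAT rose from 0.537 ± 0.723 to 19.2 ± 26.3 CPM (log2 5.14, adjusted p = 0.00273).

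SOX10 fell from 221 ± 143 to 27.7 ± 13.4 CPM (log2 fold change −3.20, SE 0.76, adjusted p = 0.00318). NEUROD1, which drives sensory neurogenesis, fell from 306 ± 376 to 0.129 ± 0.094 CPM (log2 −11.10, adjusted p = 7.80e-05). LIN28A, which blocks let-7 maturation in immature cells, fell from 372 ± 299 to 5.901 ± 3.11 CPM (log2 −5.71, adjusted p = 1.17e-07). GLI1 fell from 11.9 ± 13.3 to 1.76 ± 0.816 (log2 −2.79, adjusted p = 0.00375). The fibrillar collagen gene COL3A1 rose from 521 ± 992 to 7727 ± 10942 CPM (log2 5.04, adjusted p = 0.00283). Smooth muscle actin ACTA2 rose from 88.03 ± 146 to 3680 ± 6333 (log2 5.37, adjusted p = 0.00233). The matrix proteoglycan gene DCN rose from 25.6 ± 48.2 to 455 ± 818 (log2 5.51, adjusted p = 0.00206). On day 35 late replicate 1 read 24112 against 2265 ± 776 CPM of COL3A1 in the other 3 libraries.

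Cholinergic genes rose: 5 of 7 up and 0 down (6 and 0 over the list alone), adjusted p = 7.74e-05, but adjusted p = 0.222 with an estimated correlation. Mesenchyme and fibroblast genes rose: 7 of 13 up and 0 down (9 and 0 over the list alone), adjusted p = 0.000146, but adjusted p = 0.345 with an estimated correlation. FGF targets rose: 2 of 9 up and 0 down (5 and 0 over the list alone), adjusted p = 0.0179, but adjusted p = 0.421 with an estimated correlation. NODAL and TGF-beta targets rose: 3 of 8 up and 0 down (5 and 0 over the list alone), adjusted p = 0.0335, but adjusted p = 0.222 with an estimated correlation. Chromaffin genes rose: 4 of 11 up and 0 down, adjusted p = 0.0389, but adjusted p = 0.266 with an estimated correlation. Sensory neuron genes fell: 1 of 12 up and 6 down (1 and 7 over the list alone), adjusted p = 7.74e-05, but adjusted p = 0.222 with an estimated correlation. Melanocyte genes fell: 0 of 8 up and 4 down, adjusted p = 0.000546, but adjusted p = 0.222 with an estimated correlation. Schwann cell precursor and glia genes fell: 0 of 11 up and 6 down (0 and 8 over the list alone), adjusted p = 0.00055, but adjusted p = 0.222 with an estimated correlation. Neural crest genes fell: 0 of 14 up and 6 down (0 and 7 over the list alone), adjusted p = 0.0138, but adjusted p = 0.384 with an estimated correlation. Pluripotency genes fell: 0 of 14 up and 5 down (1 and 5 over the list alone), adjusted p = 0.00165, but adjusted p = 0.222 with an estimated correlation. Neural plate border genes fell: 0 of 11 up and 3 down (0 and 5 over the list alone), adjusted p = 0.0311, but adjusted p = 0.345 with an estimated correlation. Central nervous system progenitor genes fell: 0 of 7 up and 1 down (0 and 3 over the list alone), adjusted p = 0.0311, but adjusted p = 0.222 with an estimated correlation. Catecholamine synthesis and storage (4 of 12 rose and 0 fell, 4 and 1 over the list alone) stood at adjusted p = 0.0944, and at adjusted p = 0.000987 without late differentiation 1. Sympathoadrenal transcription factors did not pass (3 of 12 rose and 2 fell, adjusted p = 0.504); of these INSM1 fell from 66.8 ± 73.9 to 3.93 ± 4.88 CPM (log2 −3.93, adjusted p = 0.0132; lost with 1 of 8 left-out libraries, highest adjusted p = 0.0574). TFAP2B fell from 366 ± 307 to 43.5 ± 35.1 (log2 −3.10, adjusted p = 0.0283; lost with 6 of 8 left-out libraries, highest adjusted p = 0.0716). Endothelium and blood genes did not pass (0 of 8 rose and 3 fell, 1 and 4 over the list alone, adjusted p = 0.204). Equal counts were found for the other lists named when adjusted over the list alone. Median, mean and test differed in sign for the HOX paralogs 10 to 13, WNT target and neuroblastoma-associated lists, which did not pass.

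With edgeR, 4540 of 23055 tested genes (2523 higher and 2017 lower) changed between days 23 and 35; without day 35 replicate 4 the split was 2103 higher and 1324 lower. Of 87 passing genes that the rule allows here, 35 lost their call with 1 library left out. DDC (6.8 ± 9.22 against 31.6 ± 25.3, log2 −2.17, adjusted p = 0.0677; adjusted p = 0.0343 to 0.17 with 1 library left out), TH (1.37 ± 2.11 against 0.482 ± 0.539 CPM, log2 1.42, adjusted p = 0.292), DBH (11.9 ± 15.01 against 6.12 ± 6.19, log2 0.87, adjusted p = 0.618), STMN2 (1011 ± 701 against 773 ± 574, log2 0.70, adjusted p = 0.674) and CHGA (256 ± 449.8 against 36.4 ± 30.1, log2 2.38, adjusted p = 0.215; log2 0.29, adjusted p = 0.926 without day 35 replicate 2) did not pass. Settings that ended a call (adjusted p) were the libraries of the 2 days only for CHAT (0.0647), COL3A1 (0.065), DCN (0.0704), GLI1 (0.0525) and INSM1 (0.0765), no line covariate for COL3A1 (0.159), DCN (0.212) and TFAP2B (0.163) and late differentiation 1 left out for TFAP2B (0.0738). Settings that gave a call (adjusted p) were no low-count filter for DDC (0.0322) and the replicate block for DDC (0.00599).

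Over the whole course, from day 0 to day 35, HOX paralogs 1 to 9 rose and pluripotency genes fell as lists, and PHOX2A and STMN2 rose. The 2 days came from different sets, so day and set could not be separated. HAND2 rose to 343 ± 320.1 CPM, a ratio of 16400 with a 95% counting interval of 5600 to 79400 (9590 without day 35 replicate 2 to 20000 without day 35 replicate 1). PHOX2A rose from 0.0529 ± 0.04804 to 62.5 ± 81.4 CPM (log2 fold change 9.93, SE 1.69, adjusted p = 6.97e-06). GATA3 rose from 0.489 ± 0.555 to 98.7 ± 101 (log2 6.61, adjusted p = 6.92e-05). STMN2 rose from 2.28 ± 1.59 to 1011 ± 701 (log2 fold change 8.10, SE 1.35, adjusted p = 5.45e-06). DBH rose from 0.203 ± 0.112 to 11.9 ± 15.01 CPM (log2 5.80, adjusted p = 0.000473). DDC, which makes dopamine, rose from 0.0758 ± 0.0503 to 6.8 ± 9.22 (log2 6.15, adjusted p = 3.26e-05). TH rose to 1.37 ± 2.11 CPM, a ratio of 64.6 with a 95% counting interval of 22.1 to 313 (13.9 without day 35 replicate 2 to 144 without day 0 replicate 1).

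POU5F1 fell from 1353 ± 492 to 0.0572 ± 0.0524 CPM (log2 fold change −15.16, SE 0.60, adjusted p = 5.57e-20). TDGF1 reached 0 counts, at least 16800-fold lower. SOX10 was higher on day 35 (log2 3.72, adjusted p = 0.000151).

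HOX paralogs 1 to 5 rose: 14 of 15 up and 0 down, adjusted p = 4.84e-15. Their median log2 change was 10.93, 9.20 with members without reads at their bound. HOX paralogs 6 to 9 rose: 12 of 12 up and 0 down, adjusted p = 1.00e-14. Their median log2 change was 12.23, 10.09 with members without reads at their bound. Pluripotency genes fell: 0 of 14 up and 14 down, adjusted p = 4.84e-15. Their median log2 change was −8.23, −7.73 with members without reads at their bound. Sympathoadrenal transcription factors rose: 12 of 12 up and 0 down, adjusted p = 9.78e-06, but adjusted p = 0.279 with an estimated correlation. Neuronal genes rose: 15 of 16 up and 0 down, adjusted p = 7.97e-05, but adjusted p = 0.407 with an estimated correlation. Cholinergic genes rose: 7 of 7 up and 0 down, adjusted p = 0.00246, but adjusted p = 0.402 with an estimated correlation. Neural crest genes rose: 9 of 14 up and 0 down, adjusted p = 0.0103, but adjusted p = 0.402 with an estimated correlation. Mesenchyme and fibroblast genes rose: 12 of 13 up and 0 down, adjusted p = 6.88e-05, but adjusted p = 0.402 with an estimated correlation. BMP targets rose: 7 of 9 up and 0 down (8 and 0 over the list alone), adjusted p = 0.0012, but adjusted p = 0.402 with an estimated correlation. HOX paralogs 10 to 13 rose: 6 of 8 up and 0 down, adjusted p = 0.0234, but adjusted p = 0.323 with an estimated correlation. Epithelium and endoderm genes fell: 1 of 11 up and 7 down, adjusted p = 0.00073, but adjusted p = 0.0858 with an estimated correlation. Proliferation genes fell: 0 of 16 up and 13 down (0 and 14 over the list alone), adjusted p = 7.97e-05, but adjusted p = 0.414 with an estimated correlation. The chromaffin list (7 of 11 rose and 1 fell) stood at adjusted p = 0.103, at adjusted p = 0.0452 with the replicate block and at adjusted p = 0.0232 without late differentiation 1. In the other lists named, counts adjusted over the list alone were equal. The NODAL and FGF target lists, which did not pass, had medians, means and tests of different sign. With edgeR, 13475 of 23055 tested genes (7175 higher and 6300 lower) changed between days 0 and 35. Of 133 passing genes that the rule allows here, 13 lost their call with 1 library left out. CHGA (256 ± 449.8 against 27.5 ± 6.85 CPM, log2 2.65, adjusted p = 0.0879; log2 0.58, adjusted p = 0.739 without day 35 replicate 2) did not pass. Settings that gave a call (adjusted p) were DESeq2 for CHGA (0.0469), no low-count filter for CHGA (0.0328) and late differentiation 1 left out for CHGA (0.0229).

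Across adjacent days of the late set few genes passed. Between day 35 and day 40 (n = 2, 1 library per label) TH rose from 1.37 ± 2.11 to 30.3 ± 12.9 CPM (log2 fold change 4.64, SE 1.05, adjusted p = 0.027; adjusted p = 0.519 with the libraries of the 2 days only, 0.132 with no line covariate, and 0.0693, 0.223 and 0.423 without replicate 1, 3 or 4). DBH went from 11.9 ± 15.01 to 316 ± 48.5 CPM (log2 fold change 4.73, SE 1.29, adjusted p = 0.0617; adjusted p = 0.00831 with the replicate block, 0.0178 with DESeq2, 0.00492 with no low-count filter, 0.00954 with unstranded counts and 0.0226 without replicate 2). These 2 genes were chosen after the values of the last days were seen. Between days 31 and 35, LIN28A fell from 42.1 ± 23.1 to 5.901 ± 3.11 CPM (log2 fold change −2.92, SE 0.53, adjusted p = 0.015). IGDCC3, an immature neural surface gene, fell from 238 ± 152 to 42.7 ± 22.4 (log2 fold change −2.42, SE 0.43, adjusted p = 0.015). The chemerin gene RARRES2 fell from 25.3 ± 17.3 to 3.198 ± 1.52 (log2 fold change −2.90, SE 0.50, adjusted p = 0.015). The prostaglandin receptor PTGER3 rose from 0.767 ± 0.291 to 9.54 ± 6.05 (log2 fold change 3.41, SE 0.61, adjusted p = 0.015). All 4 lost their calls with the libraries of the 2 days only (adjusted p at least 0.272), with no line covariate (at least 0.246) and without replicate 3 (at least 0.448) or 4 (at least 0.301). IGDCC3, RARRES2 and PTGER3 also lost them without replicate 2 (adjusted p = 0.0827, 0.276 and 0.0994).

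Genes called by edgeR between adjacent days were 1370 higher and 1020 lower for day 11 against day 7 (247 and 154 without replicate 1; 150 and 50 without replicate 2; 660 and 824 without replicate 3; 839 and 932 with no low-count filter, 1052 and 1202 with unstranded counts and 1306 and 1375 without replicate 4), 1040 higher and 1170 lower for day 16 against day 11 (167 and 75 without replicate 1; 25 and 51 without replicate 2; 451 and 417 with no line covariate and 864 and 852 without replicate 3) and 1213 higher and 1422 lower for day 23 against day 21 (346 and 201 without replicate 1; 712 and 354 without replicate 2; 1062 and 892 without replicate 3; 1311 and 1130 with DESeq2 size factors, 1373 and 1074 with no low-count filter, 1879 and 1592 with DESeq2, 1352 and 1242 with unstranded counts and 1081 and 686 with late differentiation 1 left out), a step that also changes set. From day 23 to 25, 25 to 27, 27 to 29 and 29 to 31 edgeR called 0 genes, with 764, 1142, 551 and 580 genes at unadjusted p < 0.05. DESeq2 called 13, 26, 3 and 0 genes in these 4 steps, and edgeR with the replicate block 16, 5, 0 and 0. Without replicate 1, day 25 against day 23 gave 7 genes higher. Day 35 against day 31 gave 3 higher and 6 lower (17 and 11 with the replicate block; 7 and 4 without replicate 1; 4 and 1 without replicate 2; 0 and 0 without replicate 3; 0 and 0 without replicate 4; 25 and 11 with no low-count filter, 27 and 19 with DESeq2 and 10 and 6 with late differentiation 1 left out) and day 40 against day 35 118 higher and 76 lower (45 and 5 without replicate 1; 210 and 71 without replicate 2; 1 and 0 without replicate 3; 10 and 0 without replicate 4; 340 and 483 with DESeq2). Without replicate 1 or 2, days 11 and 16 hold 1 library each, as does day 40 without replicate 2 or 4; any library left alone in its group is assumed to vary like those of other groups.

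**Figure D2:**
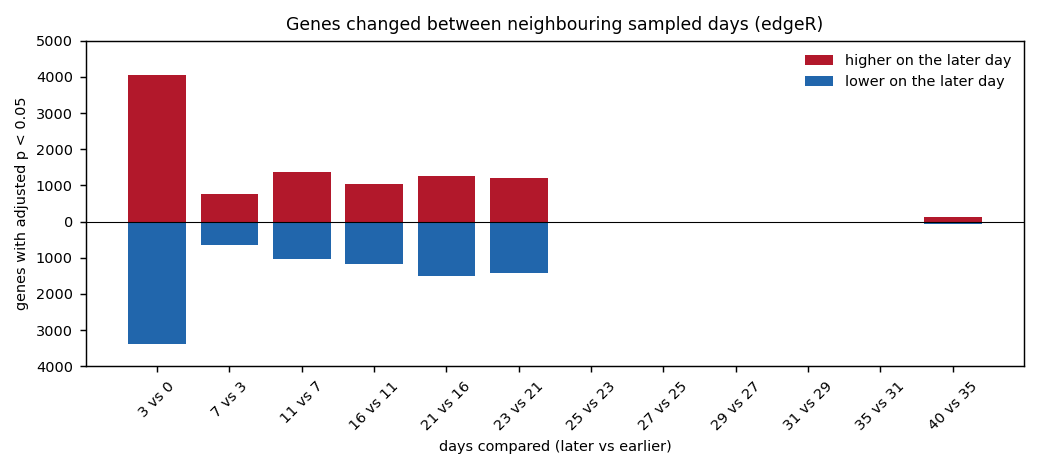
Genes with adjusted p < 0.05 for each pair of adjacent days, higher on the later day above the line and lower below it. Bars were tallest for day 3 against day 0 (4059 higher and 3385 lower) and absent for the 4 steps from day 23 to day 31. An absent bar means that no gene passed, not that none changed.

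Libraries labelled H9 and J2 differed in both sets, and most genes called in both sets differed in opposite directions. PEG3 (ENSG00000198300, chromosome 19, 56810077 to 56840728), an imprinted zinc finger gene, averaged 178 ± 61.02 CPM with label H9 and 0 counts with label J2 over days 0, 3, 7 and 21, which had both labels (n = 8 each, as for all early levels here; at least 13000-fold), and 334 ± 277 over all early libraries labelled H9 (n = 12), but 0.0106 ± 0.0218 CPM in late libraries labelled H9 and 417 ± 221 in those labelled J2 (n = 13 each; log2 −14.79, adjusted p = 7.24e-24). The long noncoding RNA LINC00839 followed it, at 19 ± 21.3 CPM against 0 counts early (at least 1490-fold higher with label H9) and 0 counts against 45.8 ± 9.73 CPM late (at least 5470-fold lower). The protocadherin gene PCDH10 had 0.138 ± 0.246 against 67.9 ± 73.8 CPM early, H9 against J2 (log2 fold change −9.17, SE 0.98, adjusted p = 7.76e-09), and 110.3 ± 73.6 against 0.235 ± 0.735 late (log2 fold change 9.91, SE 0.79, adjusted p = 3.28e-12; adjusted p = 0.131 with counts summed over days). TAFA5, a secreted brain peptide, had 0.00978 ± 0.0197 against 17.4 ± 10.95 CPM early and 12.5 ± 6.96 against 0.00832 ± 0.0211 late. The mitochondrial regulator CHCHD2 was higher with label H9 late (131 ± 18.02 against 0.109 ± 0.216 CPM, log2 10.38, adjusted p = 7.15e-17) but near 0 in both labels early (0.0813 ± 0.116 CPM over all 12 libraries labelled H9 and 0 counts in the 8 labelled J2).

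With edgeR, 6967 of 23055 genes differed between labels in days 0 to 21 (3533 higher and 3434 lower in libraries labelled H9; 2599 and 2198 without replicate 1; 2297 and 2009 without replicate 2; 1701 and 2062 without replicate 3; 1450 and 2157 with a change of at least 2-fold, 3171 and 3797 with DESeq2 size factors, 2806 and 3391 with no low-count filter, 3367 and 4290 with DESeq2, 3412 and 3700 with unstranded counts and 2434 and 3190 without replicate 4). In days 23 to 40, 7256 differed (3682 higher and 3574 lower; 1983 and 1901 without replicate 3; 3213 and 3216 without replicate 2), but 158 (51 and 107) with counts summed over days, 2 differentiations against 2, which gave 6994 (3240 and 3754) in days 0 to 21. Of 2974 genes called in both sets without summing, 2667 (89.7%) had opposite directions and 307 the same. On summed counts this was not tallied. In the early set, with label H9 against J2, primitive streak, mesoderm and axial progenitor genes were higher as a list (5 higher, 0 lower of 15, adjusted p = 0.0281, but adjusted p = 0.795 with an estimated correlation). HOX paralogs 1 to 5 were higher as a list (8 higher, 0 lower of 15, adjusted p = 0.0264, but adjusted p = 0.795 with an estimated correlation). Proliferation genes were higher (6 higher, 0 lower of 16, adjusted p = 0.032, but adjusted p = 0.846 with an estimated correlation). Neural crest genes were lower (0 higher, 5 lower of 14, adjusted p = 0.0264, but adjusted p = 0.795 with an estimated correlation). Mesenchyme and fibroblast genes were lower (0 higher, 5 lower of 13, adjusted p = 0.0281, but adjusted p = 0.795 with an estimated correlation). In the late set, mesenchyme and fibroblast genes were higher as a list (8 higher, 0 lower of 13, adjusted p = 0.0327, but adjusted p = 0.889 with an estimated correlation). Skeletal muscle genes were higher as a list (7 higher, 0 lower of 8, 7 and 1 over the list alone, adjusted p = 0.0187, but adjusted p = 0.889 with an estimated correlation). Without late differentiation 1 these late lists stood at adjusted p = 0.651 and adjusted p = 0.777. The other lists of both sets had equal counts over the list alone. Median, mean and test differed in sign for HOX paralogs 6 to 9 in both sets and, late, for the primitive streak, sympathoadrenal, catecholamine, cholinergic, NODAL and stress lists, none of which passed.

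**Figure D3:**
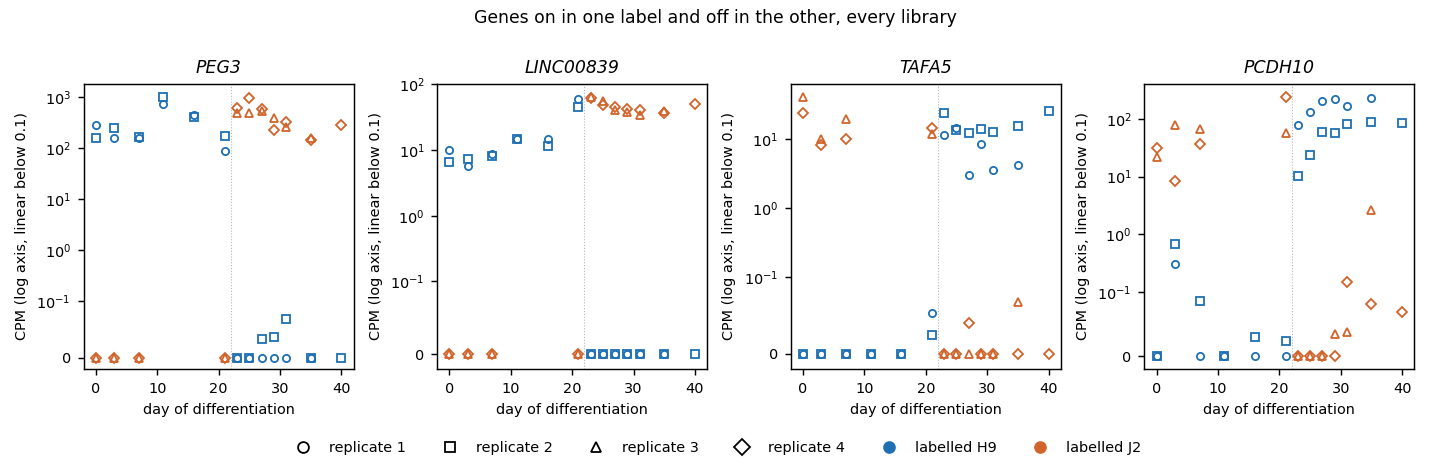
CPM (log axis) against day for 4 genes; points are libraries, coloured by label, and the dotted line parts the sets. PEG3 and LINC00839 were read in early libraries labelled H9 and late libraries labelled J2, and TAFA5 and PCDH10 the other way round; PEG3 averaged 334 CPM early with label H9 (n = 12) and 417 late with label J2.

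On day 21, the BMP target ID1 and the matrix gene POSTN were higher in libraries labelled J2, and melanocyte genes were higher in libraries labelled H9. POSTN, a matrix gene of mesenchyme, was at 0.199 ± 0.167 CPM with label H9 and 2746 ± 148 with label J2 (n = 2 each; H9 change from day 0 minus J2 change, log2 −11.80, SE 1.88, adjusted p = 0.00044). TYRP1, a melanosome enzyme, was at 30.7 ± 8.47 CPM with label H9 and 0.507 ± 0.0118 with label J2 (log2 11.90, SE 1.74, adjusted p = 0.000264). ID1, a direct BMP target, stood at 1.56 ± 0.271 against 127 ± 5.82 CPM, H9 against J2 (log2 difference −5.73, SE 0.69, adjusted p = 2.61e-05). ID3 stood at 6.89 ± 1.004 against 436 ± 47.5 (log2 difference −4.90, SE 0.80, adjusted p = 0.000501). SMAD7, a BMP and TGF-beta inhibitor, stood at 8.77 ± 0.729 against 62.2 ± 1.63 (log2 difference −2.82, SE 0.62, adjusted p = 0.00586). STMN2 stood at 2.46 ± 1.24 against 314 ± 358 (log2 difference −6.24, SE 2.06, adjusted p = 0.0491; lost with 6 of 8 left-out libraries, highest adjusted p = 0.282); these 4 genes and the lists by label were chosen after the values were seen. BMP targets as a list were higher with label J2 on day 21 (median log2 2.82, adjusted p = 1.14e-07, but adjusted p = 0.0558 with an estimated correlation), and melanocyte genes were lower (median −4.06, adjusted p = 1.20e-05, and adjusted p = 0.0176 with an estimated correlation). With edgeR the change from day 0 to day 21 differed between labels for 2653 genes (1570 higher and 1083 lower with label H9; 1581 and 1764 with no low-count filter, 1570 and 2216 with DESeq2 and 1175 and 1369 with unstranded counts). DESeq2 size factors as scaling gave 991 and 1435, with a median over all genes of −0.24 instead of −0.02, a shift of −0.22. The replicate block gave 2413 and 1753. Single libraries moved the count: 753 higher and 1075 lower without day 0 replicate 1, 419 and 764 without day 0 replicate 2, 308 and 432 without day 0 replicate 3, 640 and 634 without day 0 replicate 4, 554 and 398 without day 21 replicate 1, 1075 and 673 without day 21 replicate 2, 576 and 545 without day 21 replicate 3, 788 and 695 without day 21 replicate 4.

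**Figure D4:**
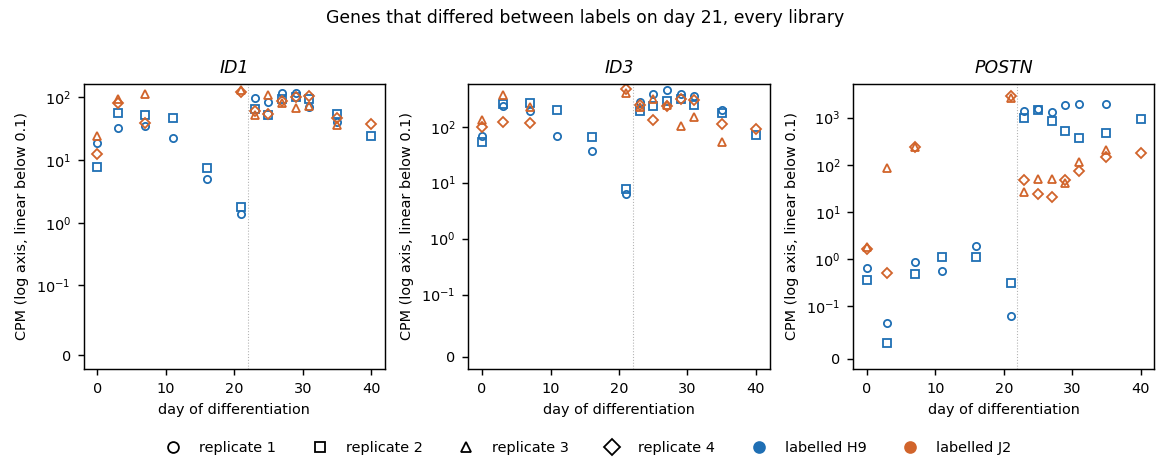
CPM (log axis) of ID1, ID3 and POSTN against day; points are libraries, coloured by label, with shape for replicate number. On day 21 POSTN averaged 0.199 CPM with label H9 and 2746 with label J2.

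From day 23 to day 35 few changes differed between labels. ANK3, which anchors channels at the axon initial segment, ended at 141 ± 47.02 against 448 ± 157 CPM on day 35, H9 against J2 (n = 2 each; log2 difference of changes −3.47, SE 0.45, adjusted p = 0.000825). The zinc finger gene ZNF814 (log2 −1.77, adjusted p = 0.0442) passed, but lost its call with 7 of 8 left-out libraries (highest adjusted p = 0.233). Settings that ended a call (adjusted p) were no low-count filter for ZNF814 (0.173) and unstranded counts for ZNF814 (0.378). With edgeR 3 genes were higher and 4 lower (422 and 290 with no low-count filter and 71 and 43 with DESeq2), and with the replicate block 123 passed. Each left-out library moved the number: 2 higher and 1 lower without day 23 replicate 1, 0 and 1 without day 23 replicate 2, 3 and 2 without day 23 replicate 3, 0 and 1 without day 23 replicate 4, 2 and 2 without day 35 replicate 1, 17 and 8 without day 35 replicate 2, 1 and 1 without day 35 replicate 3, 0 and 1 without day 35 replicate 4.

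**Figure D5:**
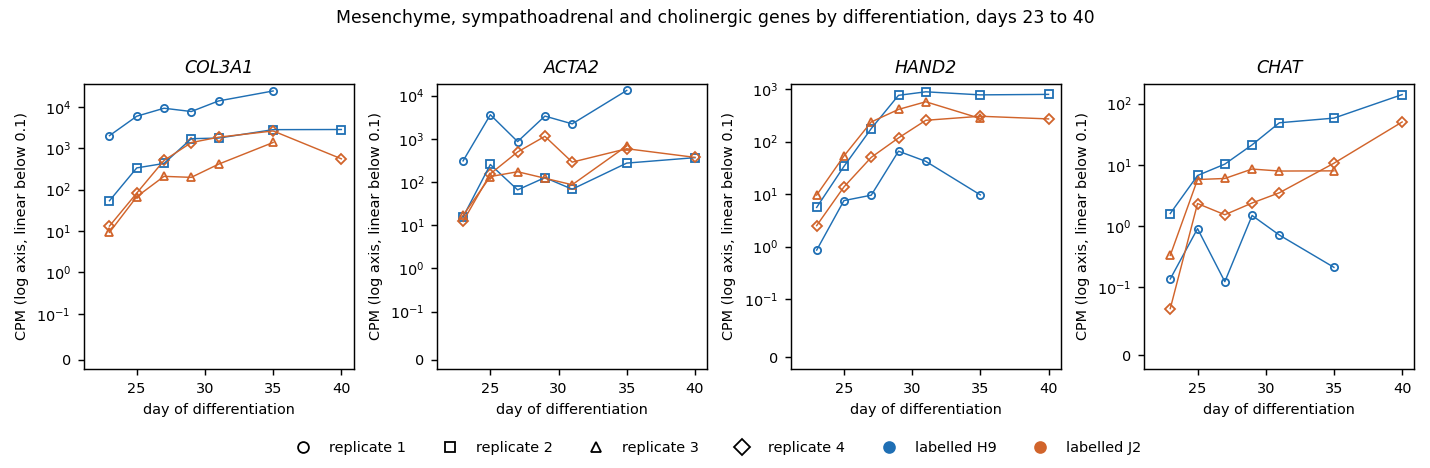
CPM (log axis) against day, days 23 to 40, for COL3A1, ACTA2, HAND2 and CHAT; points are libraries and lines join the libraries of 1 replicate number, coloured by label. Replicate 1 read 24112 CPM of COL3A1 on day 35, while the other 3 averaged 2265 ± 776 (n = 3).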

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

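The tests of the line-label, late differentiation 1 and day 21 patterns were chosen only after those results were seen; the splits were planned before. A Dixon test (95% level) on CPM of genes named, in 113 groups of gene and day or label, picked a library in 27. Chance picks about 1 in 20 groups if values are normal. All 27 were at the high end, so CPM may be skewed and this rate may not hold. The libraries picked most often were day 0 replicate 1, day 3 replicate 4, day 21 replicate 3, day 23 replicate 1, day 35 replicate 1 and day 35 replicate 2 (3 groups each).

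The values picked, in CPM, were as follows. Day 0 replicate 1 (labelled H9): CDX2 0.0879, HOXB9 0.0586, MSMO1 385. Day 3 replicate 2 (labelled H9): PCDH10 0.6896. Day 3 replicate 3 (labelled J2): HOXA9 7.05, HOXC9 2.22. Day 3 replicate 4 (labelled J2): GATA3 92.9, MSMO1 3732, SNAI2 209. Day 7 replicate 3 (labelled J2): FOXD3 23.2, SOX10 119.9. Day 21 replicate 1 (labelled H9): TAFA5 0.0538. Day 21 replicate 3 (labelled J2): CLDN4 1.15, EPCAM 2.37, STMN2 567. Day 21 replicate 4 (labelled J2): PCDH10 241. Day 23 replicate 1 (labelled H9): ACTA2 308, COL3A1 2009, DCN 97.9. Day 23 replicate 2 (labelled H9): RET 21. Day 35 replicate 1 (labelled H9): ACTA2 13176, COL3A1 24112, DCN 1682. Day 35 replicate 2 (labelled H9): CHGA 929.9, DDC 20.5, TH 4.52. Day 35 replicate 4 (labelled J2): NEUROG1 0.0813.

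Tests of a difference between groups marked 2653 genes whose change from day 0 to day 21 differed between labels, among them POSTN (log2 difference of changes −11.80), TYRP1 (log2 difference of changes 11.90). For day 35 against day 23, 7 genes did so, including ANK3 (−3.47), ZNF814 (−1.77). Between days 0 to 21 and days 23 to 40 the label difference itself differed for 9318 genes, in a test that took libraries of all days as replicates; with counts summed over days, the late label comparison alone fell from 7256 to 158 genes. The library of the TH reporter line, which no comparison used, stood above all 4 other libraries of day 31 in 4 of the 27 key genes: TH at 16.2 CPM against 0.452 to 9.702, SOX10 at 118 CPM against 15.9 to 43.8, FOXD3 at 12.6 CPM against 1.43 to 2.59 and CDX2 at 0.158 CPM against 0 to 0.0691; 23 lay between and 0 below.

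Of 20 genes that were on (at least 5 CPM) in every early library of 1 label and off (at most 0.5 CPM) in every library of the other, 12 were opposite in the late set, 0 kept their direction, 3 showed no difference and 5 could not be scored (exact sign test p = 0.000488), and all-gene differences correlated at −0.54. An exchange of the labels in 1 of the 2 sets fits these values, though they cannot show which set it would be, and CHCHD2 and ZNF248 changed between the sets under either naming. Whether both labels name the same 2 cell stocks throughout could not be told: 28 genes differed on against off between early J2 and late H9 and 18 between early H9 and late J2 (exact binomial p = 0.184). The 12 opposite genes argue against a biological switch from day 21 to 23 alike in both labels. An opposite switch, like an exchange, predicts many differences within a label (105 against 46 in crossed pairs) and remains open. Nothing was relabelled, and day comparisons within a set take the same libraries under either naming.

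Late differentiation 1 (labelled H9) stood apart on day 35, at 24112 against 2265 ± 776 CPM of COL3A1, 13176 against 515 ± 214 of ACTA2, 9.68 against 454 ± 282 of HAND2, 92.3 against 1318 ± 418 of STMN2 and 0.213 against 25.6 ± 28.2 of CHAT, replicate 1 against the other 3 (n = 3). That a few abundant genes took reads from the rest is excluded: 35 sympathoadrenal, neuronal and cholinergic genes were lower by a median of 19.5-fold (quartiles 10.8 to 53.7), while the share of the 10 most abundant genes, 10.9% against 3.66%, allows 1.08-fold. Another cell stock than late replicate 2 is excluded on the same footing, since 0 of 15 on/off genes differed between these replicates, against 14 of 17 between replicate 1 and late libraries labelled J2. The 13 mesenchyme genes were higher by a median of 7.83-fold. The design gives no group for this, so no biological explanation was tested, and a larger share of mesenchymal cells in that culture stays a possibility that bulk counts cannot settle.

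On day 21 the BMP targets were higher with label J2 (adjusted p = 1.14e-07, but adjusted p = 0.0558 with an estimated correlation), as were sympathoadrenal transcription factors (median log2 4.81, adjusted p = 0.000241, but adjusted p = 0.558 with an estimated correlation) and neuronal genes (median 4.73, adjusted p = 5.43e-06, but adjusted p = 0.558 with an estimated correlation). A constant line difference is excluded, since 6 of 9 BMP targets changed differently from day 0 to day 21. So is library scaling, since 6 did so with DESeq2 size factors. If the J2 libraries had been taken after the change to BMP4 and SHH, hedgehog targets would also be higher. Of the 7, 5 were (GLI1 8.4 against 1.87 CPM, J2 against H9). Their median log2 difference was 0.82 (adjusted p = 0.611), so this test could not tell. A line difference in response stays open, since each label had n = 2 libraries on that day.

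Each pair of days with 8 libraries was split into 4 and 4 in 35 ways, the real one included, with only those libraries fitted. For day 3 against day 0 only the real split gave as many genes (4997, highest other 996). The same held for day 35 against day 0 (8844 and 33) and day 23 (1759 and 402, by label). Late replicate numbers deviated together, and of the 8 splits that part every number the real one gave 1759 genes and the others 0; 8 are too few for a share under 0.05. For day 7 against day 3, 2 splits gave as many, the real one (385) and the split by label (3561), a known difference between the libraries; the other 33 gave 0. For day 23 against day 21, 2 splits gave as many, the real one (330) and the split with crossed labels (1123), and the other 33 gave 0. Of the 18 splits with 2 of each label, 1 per pair gave as many, or 2 for day 23 against day 21. Chance was excluded for no pair so far. For day 25 against day 23, 3 splits gave as many as the real 1 gene, with 2999 for the split by label, so chance cannot be excluded. For day 27 against 25, day 29 against 27, day 31 against 29 and day 35 against 31, the real count was 0 genes. All 35 splits then give as many, so the count tests nothing. Their highest were 1683 for the split by label, 1906 and 2659 for replicates 1 and 4 against 2 and 3, and 799 for the split by label. For labels, 3 splits are too few; 1 of the 3 gave as many genes, with 6967 real and 0 highest other early, and 7256 real and 3452 highest other late.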

How the results depend on the processing

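Late differentiation 1 left out, unstranded counts, libraries labelled H9 only and the lists with the replicate block were chosen after the data were seen. Of the numbers of genes, those that stayed within 1.5-fold in total and in higher and lower genes each were 54 of 104 with 1 library or replicate number left out, 13 of 19 with an absolute log2 change of at least 1, 1 of 2 with counts summed over days, 2 against 2, 17 of 19 with DESeq2 size factors, 9 of 19 with DESeq2 Wald test, 4 of 10 with late differentiation 1 left out, 3 of 4 with libraries labelled H9 only, 4 of 15 with libraries of the 2 days only, 8 of 15 with no line covariate, 10 of 19 with no low-count filter, 11 of 17 with the replicate block, 17 of 19 with unstranded counts. Totals of the others follow. The cause of the moved numbers was not tested, except that a fold limit can only lower a number. With an absolute log2 change of at least 1 the numbers were 5048 for day 3 against 0, 3153 for day 35 against 23, 1761 for day 11 against 7, 158 for day 40 against 35, 3607 for early labels, 3602 for late labels. With the libraries of the 2 days only the numbers were 4997 for day 3 against 0, 385 for day 7 against 3, 533 for day 21 against 16, 1759 for day 35 against 23, 8844 for day 35 against 0, 1321 for day 11 against 7, 3656 for day 16 against 11, 330 for day 23 against 21, 1 for day 25 against 23, 0 for day 35 against 31, 0 for day 40 against 35. The DESeq2 Wald test gave 1970 for day 7 against 3, 3174 for day 11 against 7, 3471 for day 23 against 21, 13 for day 25 against 23, 26 for day 27 against 25, 3 for day 29 against 27, 46 for day 35 against 31, 823 for day 40 against 35, 3786 for interaction day 21 against 0, 114 for interaction day 35 against 23. Without a line covariate the numbers were 649 for day 7 against 3, 2944 for day 35 against 23, 1649 for day 11 against 7, 868 for day 16 against 11, 1104 for day 23 against 21, 0 for day 35 against 31, 15 for day 40 against 35. With no low-count filter the numbers were 2084 for day 21 against 16, 3808 for day 35 against 23, 1771 for day 11 against 7, 16 for day 25 against 23, 18 for day 27 against 25, 36 for day 35 against 31, 316 for day 40 against 35, 3345 for interaction day 21 against 0, 712 for interaction day 35 against 23. With libraries labelled H9 only the number was 3410 for day 21 against 16. With late differentiation 1 left out the numbers were 1767 for day 23 against 21, 6 for day 25 against 23, 4 for day 27 against 25, 2 for day 29 against 27, 16 for day 35 against 31, 81 for day 40 against 35. With the replicate block the numbers were 16 for day 25 against 23, 5 for day 27 against 25, 28 for day 35 against 31, 173 for day 40 against 35, 4166 for interaction day 21 against 0, 123 for interaction day 35 against 23. With DESeq2 size factors as scaling the numbers were 139 for day 40 against 35, 2426 for interaction day 21 against 0. With unstranded counts the numbers were 5 for day 35 against 31, 159 for day 40 against 35. With counts summed over days, 2 against 2 the number was 158 for late labels.

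The number of fixed lists that passed fell with the estimated correlation from 11 to 7 for day 3 against day 0, from 4 to 2 for day 7 against 3, from 9 to 4 for day 16 against 7, from 7 to 2 for day 21 against 16, from 12 to 0 for day 35 against 23, from 12 to 3 for day 35 against 0, from 5 to 0 for early labels and from 2 to 0 for late labels. With fry, 22 lists passed for day 35 against 0, 12 for early labels and 10 for late labels; fry asks whether any member changed, and camera whether members differ from other genes. With late differentiation 1 left out, 6 lists passed for late labels, with 1 differentiation left under label H9, so that these calls rest on 1 culture. Of the list calls named, those that kept their side were 23 of 67 with camera with the estimated correlation, 58 of 60 with camera with the replicate block, 26 of 30 with camera, late differentiation 1 left out, 58 of 67 with fry with the main design.

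With 1 library left out in turn, numbers of genes ranged over 6174 to 7321 for day 3 against day 0, 667 to 1811 for day 7 against 3, 684 to 2853 for day 16 against 7, 701 to 2958 for day 21 against 16, 3282 to 4147 for day 35 against 23, 12427 to 12965 for day 35 against 0, 740 to 1828 for the interaction of days 0 and 21 and 1 to 25 for that of days 23 and 35. With 1 replicate number left out they ranged over 200 to 2681 for day 11 against 7, 76 to 2288 for day 16 against 11, 547 to 2387 for day 23 against 21, 0 to 7 for day 25 against 23, 0 to 11 for day 35 against 31, 1 to 281 for day 40 against 35, 3763 to 5624 for early labels and 3884 to 7168 for late labels, and stayed at 0 for the 3 steps from day 25 to day 31. Beyond the calls given with it, the replicate block changed no call named. The genes named were picked after their values were seen, so their calls are no fair measure of stability. With a library left out, 8 of 73 passing calls named were lost, against 182 of 449 allowed by the rule but not named. Over all passing calls that the rule allows, those kept were 3246 of 3860 with 1 library or replicate number left out, 17 of 20 with counts summed over days, 2 against 2, 516 of 522 with DESeq2 size factors, 516 of 521 with DESeq2 Wald test, 216 of 230 with late differentiation 1 left out, 82 of 118 with libraries labelled H9 only, 313 of 439 with libraries of the 2 days only, 410 of 493 with no line covariate, 518 of 522 with no low-count filter, 496 of 502 with the replicate block, 502 of 522 with unstranded counts. Over all values of these genes, passing or not, the direction was opposite in 53 of 4742 with 1 library or replicate number left out, 1 of 645 with DESeq2 Wald test, 14 of 173 with libraries labelled H9 only, 3 of 532 with libraries of the 2 days only, 7 of 617 with no line covariate, 1 of 646 with no low-count filter, 1 of 626 with the replicate block, 4 of 646 with unstranded counts. Among the genes and lists named, values with the opposite direction were −0.60 for DBH, day 35 against day 23 (without day 35 replicate 2), −0.29 for TH, day 35 against day 23 (without day 35 replicate 2), adjusted p = 0.651 for list mesenchyme and fibroblast, H9 against J2, days 23 to 40 (camera, late differentiation 1 left out). Over left-out libraries the log2 change from day 23 to day 35 ranged for DBH from −0.60 without day 35 replicate 2 to 1.68 without day 23 replicate 2 and for TH from −0.29 without day 35 replicate 2 to 2.29 without day 23 replicate 2. Depth limits genes near the floor of 3 counts in a group, for which only bounds or ratios are given, and at 21949466 to 42878200 counts per library the low-level key gene TH on day 21 and earlier rests on few counts.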

Other observations

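The genes and lists compared by label in this part were chosen after the values were seen. NEUROD4 fell from 117 ± 139 to 0.1204 ± 0.191 CPM (log2 fold change −10.07, SE 1.55, adjusted p = 3.88e-05). NEUROG1, the upstream sensory determinant, fell from 24.3 ± 34.5 to 0.0203 ± 0.0407 CPM, a ratio of 1170 with a 95% counting interval of 325 to 9690 (380 without day 23 replicate 2 to 1580 without day 23 replicate 4) for day 23 over day 35. PPP1R17, found in intermediate neural progenitors, fell from 561 ± 631 to 0.967 ± 1.22 CPM (log2 −8.75, adjusted p = 0.000695).

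HOXA13 went from 0 counts on day 0 to 3.53 ± 3.898 CPM on day 3, at least 176-fold, and HOXC10 to 0.3903 ± 0.3498 CPM, at least 18.5-fold; between days 3 and 7 HOXC10 rose again from 0.3903 ± 0.3498 to 5.42 ± 4.42 CPM (log2 3.77, adjusted p = 0.00183; adjusted p = 0.0859 with the libraries of the 2 days only). HOXA13 fell to 0.0214 ± 0.0273, a ratio of 158 with a 95% counting interval of 54.1 to 767 (110 without day 3 replicate 1 to 335 without day 7 replicate 1). On day 3 the neural crest list was higher in libraries labelled J2 (median log2 1.96, adjusted p = 0.000265, but adjusted p = 0.454 with an estimated correlation). On day 21 the sensory neuron list was higher with label J2 (median 4.77, adjusted p = 0.00382, but adjusted p = 0.558 with an estimated correlation), as was mesenchyme and fibroblast (median 2.68, adjusted p = 0.00513, but adjusted p = 0.688 with an estimated correlation).

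Not every gene followed the opposite pattern between the sets: ZNF248 averaged 41.8 ± 11.6 CPM in early libraries labelled H9 (n = 12) and 0.00429 ± 0.0121 in those labelled J2 (n = 8), and 51.5 ± 13.4 against 44.3 ± 7.32 late (n = 13 each).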
